A study of Drosophila melanogaster with 9 samples.

How the data were processed

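Gene expression was measured on 9 single-colour Affymetrix Drosophila expression arrays, each from 1 sample of sorted larval cells. Per the labels' protocols, 80 body walls of larvae of the wandering stage that ends the third instar, reared at 25 °C, were dissected and digested with protease for each sample. Cells carrying the membrane marker mCD8:GFP were then collected, by magnetic beads per the series' design text. The driver GAL4[21-7] is labelled as active in all classes of dendritic arborization (da) neurons, the sensory neurons of the larval body wall. Total RNA was extracted with the PicoPure kit and labelled with biotin, per the labels' protocols. The 3 groups were marker alone (Control), marker with ectopic Abrupt (Ab ME) and marker with ectopic Knot (Kn ME), with 3 biological replicates each.

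The deposited values were made with RMA, per the submitters' processing notes, and are taken here as log2 values. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The version, the variant used and the log base were not given in the sources used here, and base 2 was inferred from the range of the values. The array medians ranged from 1.44 to 1.67. Because RMA normalizes the probes before it summarises them, medians over probe sets need not be equal. They do not show which arrays were normalized together or whether the values were changed later, and both stay unknown. Scanner output, detection calls and hybridization dates were not used here, so neither signal over background nor batch could be examined, and the number of arrays limits the precision. RMA compresses differences between dim probe sets, and a value near the median of all values, 1.54, may be background.

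The table held 18952 probe sets. Of these, 183 control probe sets were left out of the tests and 18769 were tested. In the platform annotation 13647 tested probe sets had 1 gene symbol, 402 had several and 4720 had none. Only those with 1 symbol were named. Of these, 13544 were brought to current symbols through their gene identifier, using a gene table of the Release 6 plus ISO1 MT assembly. That table served for names and for the order of neighbouring genes, and no coordinates are reported because the annotation of the array names no build. The named probe sets covered 11982 genes, of which 1094 had more than 1 probe set; the probe set with the highest mean over the 9 arrays stood for its gene. No pair of arrays held identical values.

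Differences were estimated with limma 3.58.1 in R 4.3.3. A linear model with a term per group was fitted to all 9 arrays, so that the groups shared 1 estimate of the spread per probe set, with 6 residual and 2.44 prior degrees of freedom. Moderated 2-sided tests gave the Ab ME and Kn ME differences from Control and the difference between Kn ME and Ab ME, and a moderated F test asked for any difference among the 3 groups. Adjusted p-values are Benjamini-Hochberg values over the 18769 probe sets, with a threshold of 0.05. Log2 differences are given with the standard error (SE) of the model, and group means with the standard deviation (SD) over 3 arrays.

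Before the data were examined, 25 gene lists were fixed. They covered transcription factors of da neurons, nociceptor and mechanosensory channels, actin regulators, microtubule regulators and motors, adhesion and guidance genes, the dpr, DIP, beat and side recognition families, voltage-gated and potassium channels, ligand-gated receptors, neuropeptides and their receptors, neuronal identity genes, ecdysone response and pruning, and cell death and injury. Further lists held markers of cells that the sort could carry over (muscle, epidermis and cuticle, hemocytes, fat body, glia, trachea, and proliferating imaginal cells) and signs of sample quality (heat shock and dissociation stress, immune response, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, proteasome, respiratory chain). Each list was tested against all other named genes with camera at a preset correlation between genes of 0.01, adjusted over the 25 lists, and again with a correlation estimated for each list. The fry test, which asks whether the genes of a list move on balance in a single direction, or in its mixed form in either direction, without comparing them with other genes, was run beside it. Counts of list members that passed are given over all probe sets and adjusted over the list alone.

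The rule for named genes was also fixed before the data were examined. It took the 10 largest rises and 10 largest falls against Control, and the 5 largest of each between Kn ME and Ab ME, among genes past the threshold whose arrays did not overlap between groups. It added the 5 genes with the largest shared difference, up to 4 members of each list with the smallest p, any list member past the threshold, and always ab, kn, Ten-m, ppk, ct and w. No probe set was named ab or w in the annotation used here.

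Because both differences from Control use the same Control arrays, 100 sets of unchanged groups were simulated against shared controls. Each probe set was drawn on its own, with the SD of its group. The 3 Control arrays cannot be split into sets of 2 or more. Alternatives planned before the data were examined were another quantile normalization, centring each array on its median, leaving out probe sets below the 40th percentile of the mean, a variance prior with trend and robust estimation, array weights, the replicate number as a block, fits of only the 6 arrays compared, leaving out each array in turn, a log2 difference of at least 1, an adjusted p under 0.01, 1 probe set per gene, and the mean of a gene's probe sets. The mean of the hemocyte list as a covariate was added after the data were seen.

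The code was tested on simulated data of 18769 probe sets with 200 changed by log2 sizes of 1, 2 or 3. When the groups shared 1 SD per probe set, calls were false in 3.01% of cases for Ab ME against Control, 7.19% for Kn ME against Control and 3.55% for Kn ME against Ab ME. Of the probe sets changed by 1, 2 and 3, the test recovered 33.8%, 75.8% and 84.8% for Ab ME, 29.4%, 77.3% and 87.9% for Kn ME, and 32.4%, 80.3% and 92.4% for Kn ME against Ab ME. When each group kept its own observed SD, 77, 62 and 23 calls were false in the same order of comparisons, or 34.7%, 30.1% and 13.2% of the calls. The spread differed between groups in the real data, with a median SD of 0.317 in Control, 0.175 in Ab ME and 0.209 in Kn ME. The simulated excess of false calls appeared in each comparison, so the adjusted p-values may be too small. The simulated SDs were themselves estimated from 3 arrays, which makes the simulated spread more unequal, so the size of the excess is uncertain. For Kn ME against Ab ME the direction is open too. There the real calls rose from 97 to 241 with only the 6 arrays compared and to 326 with array weights.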

Results

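Gene expression profiles were obtained from cells of the larval body wall, sorted by a marker driven in da neurons, from animals expressing this marker, mCD8:GFP, alone (Control) or together with Abrupt (Ab ME) or Knot (Kn ME). Abrupt (gene ab) and Knot (gene kn) are transcription factors known for shaping the dendrites of different da neuron classes. Misexpression in all classes asks which transcripts differ when either factor is present outside its usual cells. Each group held 3 arrays, with medians of 1.59, 1.67 and 1.61 log2 units in Control, 1.47, 1.45 and 1.44 in Ab ME, and 1.52, 1.496 and 1.53 in Kn ME. Replicates correlated across probe sets at r = 0.93 to 0.944 in Control, 0.984 to 0.985 in Ab ME and 0.974 to 0.977 in Kn ME. The first principal component held 51% of the variance and placed the Kn ME arrays (7.0 to 17.6) between Control (-85.3 to -46.7) and Ab ME (52.3 to 57.9).

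**Figure D1:**
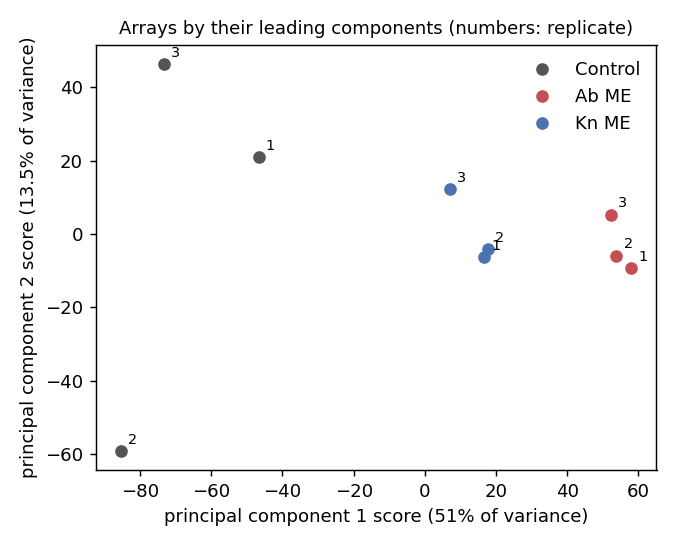
Scores of the 9 arrays on the first principal component (x axis, 51% of variance) and the second (y axis, 13.5%), a point per array, coloured by group and numbered by replicate. The Control arrays spread from -59.2 to 46.4 on the second component, more widely than the arrays of the other groups.

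The misexpressed genes could not be followed directly. No probe set was named ab here. The brightest kn probe set averaged 2.76 ± 1.53 in Control, 0.61 ± 0.08 in Ab ME and 0.61 ± 0.08 in Kn ME (mean ± SD, n = 3). The kn values of Control were 1.00, 3.75 and 3.53, and the differences did not pass the test (Ab ME -2.15, SE 0.62, limma adjusted p = 0.0534; Kn ME -2.16, SE 0.62, adjusted p = 0.0897). Without Control replicate 1 they did, with adjusted p = 0.000101 and 0.000218. Over 17 alternatives, changes of processing among them, the Ab ME difference passed in 5 (adjusted p up to 0.138 in the others) and that of Kn ME in 2 (up to 0.223). A second kn probe set differed by -0.12 and -0.01. The kn signal was thus not higher on the arrays labelled Kn ME. Whether either probe set matches the introduced sequence is not given here, so kn does not check the labels, which are used as given.

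Ten-m, a teneurin adhesion molecule, rose in both groups. It averaged 7.27 ± 0.29 in Control, 9.20 ± 0.05 in Ab ME and 8.60 ± 0.11 in Kn ME (n = 3 each), differences of 1.93 (SE 0.17, limma adjusted p = 0.000358) and 1.33 (SE 0.17, adjusted p = 0.00514) log2 units. The difference between Kn ME and Ab ME, -0.59, did not pass (adjusted p = 0.243). For ct, a homeodomain factor of da neuron identity, the brightest probe set rose by 1.62 in Ab ME (SE 0.19, adjusted p = 0.00128) and by 1.10 in Kn ME (SE 0.19, adjusted p = 0.0162). Another ct probe set fell by 2.02 (adjusted p = 0.00358) and fell by 1.59 (adjusted p = 0.021), and the mean of the ct probe sets passed in neither group (adjusted p = 0.138 and 0.544). In Kn ME the rise of ct was also lost without Kn ME replicate 1 (adjusted p = 0.0628) or replicate 2 (0.0648) and with another quantile normalization (0.0713), with the trend and robust prior, and with only the 6 arrays compared. In all, the rise of ct passed in 11 of 17 alternatives in Kn ME (adjusted p up to 0.544 in the others) and in 16 in Ab ME. For ppk, a channel subunit of nociceptive class IV neurons, the differences of -2.28 in Ab ME and -1.85 in Kn ME did not pass (adjusted p = 0.0682 and 0.193), with Control values of 1.99, 1.64 and 4.84. Without Control replicate 3 both passed (adjusted p = 0.00386 and 0.0315), and without Control replicate 2 that of Ab ME did (0.0363). The ppk difference of Ab ME passed in 5 of 17 alternatives (adjusted p up to 0.167 in the others) and that of Kn ME in 1 (up to 0.358).

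**Figure D2:**
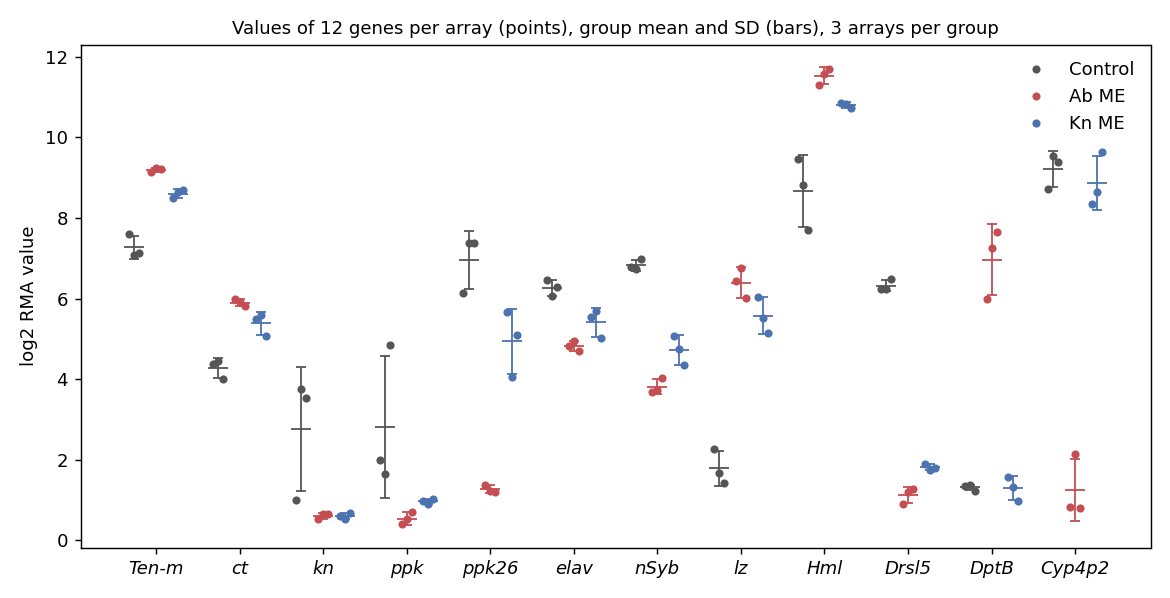
Log2 RMA values (y axis) of 12 genes (x axis), with a point per array and bars for the group mean and SD of 3 arrays. Ten-m, lz and Hml, a blood cell gene chosen after its values were seen, lie above Control in both misexpression groups, elav, nSyb and Drsl5 lie below it, Cyp4p2 is low in Ab ME alone and DptB is high in Ab ME alone. The kn and ppk values vary among the Control arrays.

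With ectopic Abrupt, blood cell genes and some antimicrobial peptide genes stood among the largest rises, while another peptide gene, Drsl5, a cytochrome P450, a nociceptor channel subunit, and single muscle and neuronal genes fell. DptB, an antimicrobial peptide gene, rose from 1.31 ± 0.07 to 6.97 ± 0.88 (n = 3 each) (log2 difference 5.65, SE 0.38, limma adjusted p = 0.000157). The crystal cell transcription factor lz, a blood cell gene, rose by 4.602 log2 units (SE 0.31, adjusted p = 0.000157). Cyp4p2 fell from 9.21 ± 0.44 to 1.25 ± 0.78 (-7.96, SE 0.46, adjusted p = 7.74e-05), and ppk26, a subunit of a nociceptive channel of class IV neurons, fell by 5.69 (SE 0.45, adjusted p = 0.000242). The lower mean of each of DptB, Cyp4p2 and ppk26 lies below the median of all values, 1.54, and that of lz close to it, where signal over background is unknown, so the sizes of these differences are uncertain. The synaptic vesicle gene nSyb fell by 3.01 log2 units (SE 0.20, adjusted p = 0.000157).

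Other rises with large differences in Ab ME were Mtk, an antimicrobial peptide gene (5.84, SE 1.06, adjusted p = 0.00895), mthl6 (4.99), CG42369 (4.73), CG8745 (4.70), Cyp6a13 (4.68), CG31431 (4.66) and CG15695 (4.62). PPO2 and PPO1, prophenoloxidases of crystal cells, rose by 5.30 and 4.96 log2 units, with Control SDs of 3.11 and 2.99. Their adjusted p of 0.0273 and 0.0295 went past 0.05 without Control replicate 2, without Control replicate 3 or without any single Ab ME array, reaching 0.0855 and 0.0934. In all, each passed in 11 of 17 alternatives. Large falls were also seen for CG7924 (-6.01), Obp56d, an odorant binding protein gene (-5.74), IA-2 (-5.64), CG31323 (-5.49), CG32572 (-5.42), Drsl5 (-5.19, SE 0.15, adjusted p = 3.44e-06), CG15353 (-5.17) and the cuticle protein gene Cpr65Aw (-5.13). Other IA-2 probe sets differed by -1.72 (adjusted p = 0.00421) and -0.25 (0.537), and the mean of all IA-2 probe sets by -2.54. In all, 2622 of 18769 probe sets passed, 1637 higher and 985 lower, or 1343 and 714 named genes. At least a 2-fold difference was found in 2073 of the 2622. Over all probe sets, 34.9% had no overlap between the arrays of the groups, against 10% by chance.

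Single genes of several neuronal lists fell in Ab ME, while most genes of each list did not pass. Of 33 neuronal identity genes measured, 12 fell and 1 rose, or 14 and 2 adjusted over the list alone (camera adjusted p = 3.27e-06; adjusted p = 0.0555 with an estimated correlation). The falls included cpx (-2.61), VAChT, the vesicular acetylcholine transporter (-2.84), and the neuronal RNA-binding gene elav (-1.45, SE 0.20, adjusted p = 0.00297). The gene that rose was shi, the dynamin gene (1.26), named after its values were seen. Of 38 voltage-gated and potassium channel genes 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.000821; adjusted p = 0.0555 with an estimated correlation). The brightest SK probe set (-2.56) and Ih (-3.09) fell, and stj, a calcium channel subunit, rose (2.45). The 3 other SK probe sets did not pass (0.13, -0.015 and -1.92), and the mean of the SK probe sets differed by -1.09. In the dpr, DIP, beat and side families 11 of 51 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.43e-05; adjusted p = 0.0714 with an estimated correlation). An example is dpr12 (-1.71, or -0.85 for the mean of its probe sets). Among 54 neuropeptide and receptor genes 4 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00254; adjusted p = 0.0555 with an estimated correlation). The peptide processing enzymes amon (-3.08) and Pal2 (-2.50) fell and Nplp2 (3.09) rose. Ligand-gated receptors had 1 rise, nAChRbeta3 (2.49), and 0 falls of 42, also adjusted over the list alone, against a list median of -0.18 (camera adjusted p = 0.0172; adjusted p = 0.0714 with an estimated correlation). The hemocyte score of these arrays, the mean log2 value over the list, was 8.21, 8.24 and 8.32 against 7.13, 6.49 and 6.02 in Control.

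Regulators of neuronal form moved both ways in Ab ME. Of 70 adhesion and guidance genes 17 fell and 5 rose, or 22 and 7 adjusted over the list alone (camera adjusted p = 0.000486; adjusted p = 0.0714 with an estimated correlation). The adhesion gene klg (-3.72) and the netrin receptor unc-5 (-2.88, or -1.87 for the mean of its probe sets) fell while Ten-m rose. Among 33 transcription factors of da neurons 3 fell and 4 rose, or 5 and 4 adjusted over the list alone, around a median of -0.34 (camera adjusted p = 0.0336; adjusted p = 0.0737 with an estimated correlation). Antp (-2.75, or -1.32 for that mean) fell and da (1.10) rose. Of 28 actin regulators 8 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.0714 with an estimated correlation). Arpc1, a subunit of the Arp2/3 complex, rose by 3.98 (SE 0.28, adjusted p = 0.00019), the formin gene dia by 2.37 and ena by 1.38. Ecdysone response and pruning genes had 5 falls and 2 rises of 28, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00254; adjusted p = 0.0737 with an estimated correlation). The falls included ImpE2 (-4.90) and ImpL2 (-2.64). The muscle score of these arrays was 3.32, 3.62 and 3.995 against 5.198, 6.01 and 5.79 in Control.

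Single markers of other cell types rose or fell in Ab ME. Of 28 hemocyte genes 22 rose and 0 fell, or 23 and 1 adjusted over the list alone (median 1.41, camera adjusted p = 6.52e-10; adjusted p = 0.0973 with an estimated correlation). Among the rises were the scavenger receptor Sr-CI (3.02, SE 0.22), the GATA factor srp (2.53) and the collagen gene vkg (1.76). Proliferation genes had 10 rises and 0 falls of 29, or 17 and 0 adjusted over the list alone (camera adjusted p = 8.76e-07; adjusted p = 0.0555 with an estimated correlation). The cyclin gene CycB (2.57) and the replication gene dup (3.43) rose. Muscle genes had 13 falls and 1 rise of 22, or 14 and 1 adjusted over the list alone (median -2.31, camera adjusted p = 6.52e-10; adjusted p = 0.0737 with an estimated correlation). Mf (-3.72), Tm2 (-3.37) and up, a troponin gene (-3.41), fell. Epidermis and cuticle genes had 41 falls and 2 rises of 140, or 51 and 2 adjusted over the list alone (camera adjusted p = 1.34e-13; adjusted p = 0.0555 with an estimated correlation). Ddc, dopa decarboxylase, fell by 4.41 on the log2 scale. Glial genes had 7 falls and 1 rise of 22, or 9 and 2 adjusted over the list alone (camera adjusted p = 5.62e-05; adjusted p = 0.0714 with an estimated correlation). The innexins Inx2 (-3.35) and ogre (-3.32) fell. Tracheal genes had 6 falls and 1 rise of 13, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00697; adjusted p = 0.0737 with an estimated correlation). The chitin deacetylase serp (-3.55) fell and sty (1.66) rose.

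Mitochondrial ribosomal protein genes had 13 rises and 0 falls of 69 in Ab ME, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.52e-07; adjusted p = 0.0864 with an estimated correlation). An example is mRpL1 (1.62). Respiratory chain genes had 12 rises and 0 falls of 75, or 13 and 0 adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.158 with an estimated correlation). Cytosolic ribosomal protein genes had 2 rises of 41 and 0 falls, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.00523; adjusted p = 0.375 with an estimated correlation). The proliferation score of the same arrays was 4.03, 4.30 and 4.31 against 3.11, 2.81 and 3.03 in Control. The remaining 7 lists did not pass. Immune response genes had 7 rises and 1 fall of 22, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.105). AttD (3.34) and PGRP-LF (3.31) rose, and Drsl5 was the fall. Fat body genes had 6 rises and 5 falls of 28, or 8 and 9 adjusted over the list alone (adjusted p = 0.649). Microtubule regulators and motors had 6 and 4 of 36, also adjusted over the list alone (adjusted p = 0.8). The microtubule-binding genes tau (-3.35) and futsch (-3.04, or -1.44 for the mean of its probe sets) fell. Heat shock and dissociation stress genes had 2 rises and 5 falls of 18, or 4 and 6 adjusted over the list alone (adjusted p = 0.155), with Hsp26 (-2.12) lower. Cell death and injury genes had 4 rises and 0 falls of 27, or 5 and 0 adjusted over the list alone (adjusted p = 0.649), with the caspase gene Dcp-1 (2.10) higher. Nociceptor and mechanosensory channels had 1 rise, ppk29 (1.49), and 2 falls of 25, or 1 and 1 adjusted over the list alone (adjusted p = 0.0564). Proteasome genes had 0 of 40 past the limma test, also adjusted over the list alone (camera adjusted p = 0.21), among 5665 probe sets at an unadjusted limma p under the same threshold over all genes.

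Of the 25 lists, 18 passed camera in Ab ME and 20 passed fry, but 0 passed camera with estimated correlations, for which fry and the counts of single genes are the other measures. With another quantile normalization the calls of actin regulators (adjusted p = 0.163), cytosolic ribosomal proteins (0.163), ligand-gated receptors (0.234), neuropeptides (0.0789) and the respiratory chain (0.201) were lost. Heat shock (0.0163) and proteasome genes (0.013) passed as lower. The share of calls that were higher was 62.4% as deposited, 49.6% (899 of 1814) after another quantile normalization and 76.2% (2384 of 3127) after centring, which moved the median difference of all probe sets by 0.17. The median signs of fat body, heat shock, microtubule and proteasome genes turned with centring, and that of cell death genes with quantile normalization. The count of 2622 became 1426, 1407 and 1400 without Ab ME replicates 1, 2 and 3, 1726 with only the 6 arrays compared and 3249 without Control replicate 1. In simulated data with unequal spread as in these groups and 200 changed probe sets, 77 calls were false beside 145 recovered, or 34.7%. This share depends on the number changed and is no estimate for the 2622.

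**Figure D3:**
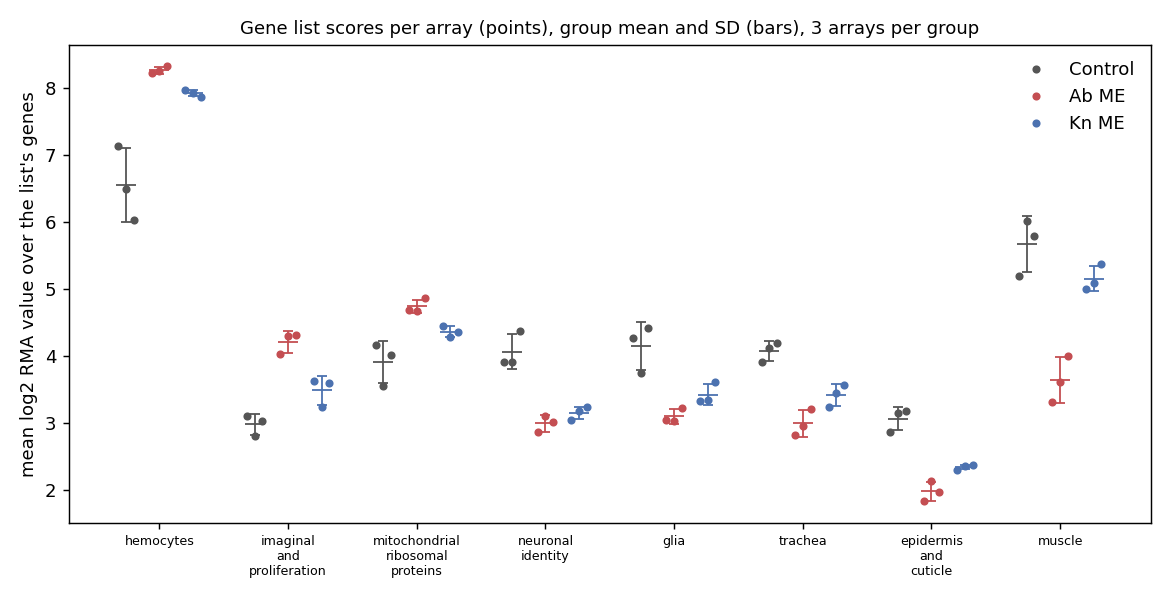
Mean log2 RMA value over the genes of 8 lists (y axis) on each array, with a point per array and bars for the group mean and SD of 3 arrays. The hemocyte score was 6.02 to 7.13 in Control, 8.21 to 8.32 in Ab ME and 7.87 to 7.96 in Kn ME, while neuronal identity, glial, tracheal and cuticle scores lay below Control in both misexpression groups.

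With ectopic Knot, on the arrays labelled Kn ME, 11 of 28 hemocyte genes were higher and 8 of 33 neuronal identity, 5 of 22 glial and 18 of 140 cuticle genes lower than in Control. With an estimated correlation these lists did not pass camera (adjusted p = 0.129, 0.0501, 0.12 and 0.0501). The crystal cell factor lz rose from 1.80 ± 0.43 to 5.57 ± 0.46 (n = 3 each) (log2 difference 3.78, SE 0.31, limma adjusted p = 0.0013). Best1, a bestrophin chloride channel gene, rose by 15.8-fold (log2 3.98, SE 0.38, adjusted p = 0.00213). Drsl5, a drosomycin-like peptide gene, fell from 6.32 ± 0.14 to 1.82 ± 0.07 (-4.50, SE 0.15, adjusted p = 1.13e-05). The Control mean of lz and the Kn ME mean of Drsl5 lie close to 1.54, the median of all values, where signal over background is unknown, so these sizes are uncertain. The synaptic gene nSyb fell by 2.10 log2 units (SE 0.20, adjusted p = 0.00218).

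Large rises in Kn ME were also those of mthl6 (4.13), CG7214 (3.87, SE 0.27, adjusted p = 0.000518), the scavenger receptor Sr-CIV (3.75), Cyp6a23 (3.74), CG17855 (3.64) and kar (3.49). Large falls were those of the noncoding RNA gene lncRNA:CR33948 (-4.39), CG7924 (-4.25), CG31323 (-3.88), CG13578 (-3.71), CG14664 (-3.67), CG11317 (-3.52), CG9813 (-3.48) and Cib2 (-3.36). Cyp4ac1 (3.79), CG31431 (3.55) and CG7906 (-3.70) also belonged to the 10 largest of their direction, but lost the call without Kn ME replicate 1 (adjusted p = 0.0976, 0.0719 and 0.056) and replicate 2 (0.107, 0.0695 and 0.082). Without Kn ME replicate 3 Cyp4ac1 (0.0781) and CG7906 (0.0554) lost it too, as did Cyp4ac1 without any single Ab ME array (up to 0.0566). A total of 992 probe sets passed, 626 higher and 366 lower, or 501 and 278 named genes, and 848 differed by at least 2-fold. The share of all probe sets without overlap was 21.8%, against 10% by chance.

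Single neuronal genes fell in Kn ME, on arrays with hemocyte scores of 7.96, 7.93 and 7.87. Of 33 neuronal identity genes 8 fell and 0 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 5.72e-07; adjusted p = 0.0501 with an estimated correlation). Voltage-gated and potassium channel genes had 2 falls, the brightest SK probe set (-2.44) and Ih (-3.29), and 1 rise, stj (2.50), of 38, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.000716; adjusted p = 0.0501 with an estimated correlation). In the dpr, DIP, beat and side families 3 of 51 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.000205; adjusted p = 0.1 with an estimated correlation). The 3 other SK probe sets did not pass (-0.21, 0.04 and -1.93), and the mean of the SK probe sets differed by -1.13. Neuropeptide and receptor genes had 2 falls and 1 rise of 54, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.00825; adjusted p = 0.0571 with an estimated correlation). Pal2 (-2.26) fell and Nplp2 (2.32) rose. Nociceptor and mechanosensory channels had 1 fall, ppk26, and 0 rises of 25, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.122 with an estimated correlation). That fall of ppk26 (-2.03, SE 0.45, adjusted p = 0.0393) was lost without Control replicate 2 (0.0913), Control replicate 3 (0.0852), any Ab ME array (up to 0.0713), Kn ME replicate 2 (0.102) or replicate 3 (0.0902), and in a fit of only the 6 arrays compared (0.127). In all, it passed in 7 of 17 alternatives. Adhesion and guidance genes had 6 falls and 3 rises of 70, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.0393; adjusted p = 0.225 with an estimated correlation). Both klg (-3.10) and unc-5 (-2.41, or -1.47 for the mean of its probe sets) fell. Actin regulators had 4 rises and 1 fall of 28, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.000716; adjusted p = 0.0501 with an estimated correlation). Ced-12, an engulfment gene, rose by 1.43 (SE 0.15, adjusted p = 0.00266).

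Among markers of other cell types, 11 of 28 hemocyte genes rose and 0 fell in Kn ME, or 21 and 0 adjusted over the list alone (median 1.23, camera adjusted p = 5.17e-11; adjusted p = 0.129 with an estimated correlation). Sr-CI (2.18), srp (2.06) and vkg (1.44) were among them. Epidermis and cuticle genes had 18 falls and 0 rises of 140, or 34 and 2 adjusted over the list alone (camera adjusted p = 1.7e-11; adjusted p = 0.0501 with an estimated correlation). The cuticle protein gene Cpr78Cc (-3.21) and Ddc (-2.48) fell. Glial genes had 5 falls and 1 rise of 22, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.000205; adjusted p = 0.12 with an estimated correlation). Gs2, glutamine synthetase (-2.45), and Inx2 (-1.70) fell. Muscle genes had 0 of 22 past the limma test, or 1 rise and 1 fall adjusted over the list alone, around a median of -0.56 (camera adjusted p = 0.00107; adjusted p = 0.298 with an estimated correlation). Tracheal genes had 4 falls and 1 rise of 13, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.129 with an estimated correlation). Proliferation genes had 4 rises and 0 falls of 29, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00715; adjusted p = 0.16 with an estimated correlation). Mitochondrial ribosomal protein genes had 1 rise and 0 falls of 69, or 0 and 0 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.000628; adjusted p = 0.252 with an estimated correlation).

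The remaining 11 lists did not pass in Kn ME. Transcription factors of da neurons had 2 rises and 0 falls of 33, also adjusted over the list alone (camera adjusted p = 0.136). Ecdysone response genes had 1 and 2 of 28, also adjusted over the list alone (adjusted p = 0.0826). Ligand-gated receptors had 1 and 0 of 42, or 0 and 0 adjusted over the list alone (adjusted p = 0.0507). Respiratory chain genes had 1 and 0 of 75, or 0 and 0 adjusted over the list alone (adjusted p = 0.0507). Immune response genes had 2 rises, PGRP-LF (2.45) among them, and 1 fall of 22, also adjusted over the list alone (adjusted p = 0.674). Fat body genes had 3 and 2 of 28, or 5 and 4 adjusted over the list alone (adjusted p = 0.566). Heat shock genes had 1 and 1 of 18, or 3 and 3 adjusted over the list alone (adjusted p = 0.312), and cell death genes had 1 and 0 of 27, or 2 and 1 adjusted over the list alone (adjusted p = 0.674). Microtubule regulators had 2 and 2 of 36, or 4 and 5 adjusted over the list alone (adjusted p = 0.964), with a median of 0.15 but a mean of -0.01 and a camera direction of lower. Cytosolic ribosomal protein genes (of 41, adjusted p = 0.675) and proteasome genes (of 40, adjusted p = 0.287) had 0 past the limma test, also adjusted over the list alone, among 3711 probe sets at an unadjusted limma p under the same threshold over all genes.

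In Kn ME 14 of the 25 lists passed camera and 16 passed fry, and 0 passed camera with estimated correlations. With another quantile normalization the calls of mitochondrial ribosomal proteins (adjusted p = 0.0725), neuropeptides (0.0993) and nociceptor channels (0.152) were lost. That of ecdysone response genes was gained (0.027), while cytosolic ribosomal genes turned to lower (0.608). With centring, ecdysone response genes passed as lower and respiratory chain genes as higher (0.0322 each), the medians of fat body and proteasome genes turned, and the median difference of all probe sets moved by 0.11. The share of calls that were higher was 63.1% as deposited, 48.1% (399 of 830) after another quantile normalization and 72.4% (830 of 1147) after centring. The count of 992 became 1609 without Control replicate 1, 640 without Ab ME replicate 2, 409, 347 and 532 without Kn ME replicates 1, 2 and 3, 589 with array weights and 337 with only the 6 arrays compared. In simulated data with the unequal spread and 200 changed probe sets, 62 calls were false beside 144 recovered, or 30.1%, a share that depends on the number changed.

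The groups with ectopic Knot and ectopic Abrupt differed in fewer genes. Cyp4p2 was at 8.87 ± 0.68 on the arrays labelled Kn ME and at 1.25 ± 0.78 in Ab ME (n = 3 each) (log2 difference 7.62, SE 0.46, limma adjusted p = 0.00089), and Cyp4p1, a neighbouring cytochrome P450 gene, was higher by 4.75 (SE 0.40, adjusted p = 0.00484). CG7214 was higher by 4.21 (SE 0.27, adjusted p = 0.000899), at 4.999 in Kn ME against 0.79 in Ab ME and 1.13 in Control. DptB differed by -5.67 (SE 0.38, adjusted p = 0.00118), at 1.29 in Kn ME and 1.31 in Control. The lower values of Cyp4p2, CG7214 and DptB lie below 1.54, the median of all values, so these sizes are uncertain too. CG10553 (-3.14, adjusted p = 0.00693) and Arpc1 (-2.76, adjusted p = 0.00693) were also lower.

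A total of 97 probe sets passed, 50 higher and 47 lower in Kn ME, or 35 and 37 named genes, and 94 differed by at least 2-fold. For 19.5% of all probe sets the arrays did not overlap, against 10% by chance. For 74 of the 97 the Kn ME mean lay between those of Control and Ab ME, for 18 the Control mean lay between and for 5 that of Ab ME. Among the largest differences, IA-2 (5.19, adjusted p = 0.0342), CG16704 (3.81, adjusted p = 0.0342), CG10859 (-3.97, adjusted p = 0.0152), Mst57Dc (-3.45, adjusted p = 0.0172) and CG13375 (-2.92, adjusted p = 0.0366) each passed. They all lost the call without Kn ME replicate 1, 2 or 3, with adjusted p up to 0.139, 0.139, 0.0758, 0.0789 and 0.144. All but IA-2 also lost it without Ab ME replicate 2 (up to 0.147 for CG13375), and IA-2 and CG13375 without Ab ME replicate 3 (0.0724 and 0.112). It was also lost by CG16704 and CG10859 without Ab ME replicate 1 (0.0824 and 0.0515) and by CG16704 without Control replicate 3 (0.05). The mean of the IA-2 probe sets differed by 2.12 and did not pass. For ppk26 the difference of 3.66 (SE 0.45, adjusted p = 0.017) was lost without Ab ME replicates 1 (0.0582) and 2 (0.0893) and Kn ME replicates 1 (0.0564) and 3 (0.0761).

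By camera at the preset correlation, muscle genes had the smallest p between these groups. Of 22, 6 were higher in Kn ME than in Ab ME and 0 lower, or 12 and 0 adjusted over the list alone (median 1.78, camera adjusted p = 2.19e-14; adjusted p = 0.164 with an estimated correlation). The differences were 3.01 for Mf (SE 0.36, adjusted p = 0.0154), 2.95 for Tm2 (SE 0.37, adjusted p = 0.0172) and 2.66 for up (SE 0.34, adjusted p = 0.0186). Each was lost without Ab ME replicate 1 or 2 or without any single Kn ME array, with adjusted p up to 0.0856, 0.0893 and 0.0993, and Mf also lost it for the mean of its probe sets (0.096). The muscle score was 5.002, 5.09 and 5.37 in Kn ME against 3.32, 3.62 and 3.995 in Ab ME.

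Other lists that passed between Kn ME and Ab ME held few single genes past the limma test, among 1643 probe sets at an unadjusted limma p under the same threshold. Higher in Kn ME were epidermis and cuticle genes (1 of 140, or 10 adjusted over the list alone; camera adjusted p = 7.17e-06; adjusted p = 0.186 with an estimated correlation) and adhesion and guidance genes (0 of 70, also adjusted over the list alone; camera adjusted p = 0.000203; adjusted p = 0.164 with an estimated correlation). Ecdysone response genes were also higher (1 of 28, or 3 adjusted over the list alone; camera adjusted p = 0.00371; adjusted p = 0.186 with an estimated correlation). The same direction held for glial genes (1 of 22 higher, or 3 and 1 lower adjusted over the list alone; camera adjusted p = 0.00587; adjusted p = 0.259 with an estimated correlation) and for the dpr, DIP, beat and side families (0 of 51, also adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.272 with an estimated correlation). It held for tracheal genes as well (0 higher and 1 lower of 13, or 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.259 with an estimated correlation). Lower in Kn ME were proliferation genes (0 of 29, or 1 adjusted over the list alone; median -0.75; camera adjusted p = 4.45e-08; adjusted p = 0.138 with an estimated correlation). Hemocyte genes were lower too (0 of 28, also adjusted over the list alone; median -0.33; camera adjusted p = 0.000567; adjusted p = 0.318 with an estimated correlation). Mitochondrial ribosomal proteins (0 of 69; camera adjusted p = 1.72e-05; adjusted p = 0.259 with an estimated correlation) and cytosolic ribosomal proteins (0 of 41; camera adjusted p = 3.03e-05; adjusted p = 0.272 with an estimated correlation) were lower as well, with 0 genes adjusted over the list alone. So was the respiratory chain (0 of 75, also adjusted over the list alone; camera adjusted p = 0.0195; adjusted p = 0.272 with an estimated correlation). The single genes that passed were Pcp, a cuticle gene (2.20), ImpL2 (1.59), Inx2 (1.65) and sty (-0.84). Pcp and sty lost the call without any single array of Ab ME or Kn ME, with adjusted p up to 0.145 and 0.147, and sty also for the mean of its probe sets. In all, Pcp kept the call in 10 of 17 alternatives and sty in 7. Inx2 lost it without Ab ME replicates 1 and 3 and each Kn ME array (up to 0.114), and ImpL2 without Ab ME replicate 2 (0.062) and Kn ME replicates 1 (0.0564) and 3 (0.07).

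For the remaining 13 lists camera did not pass between Kn ME and Ab ME. Immune response genes had 1 fall of 22, DptB, or 2 rises and 4 falls adjusted over the list alone (camera adjusted p = 0.0521). Heat shock genes had 0 of 18, or 4 and 1 adjusted over the list alone (adjusted p = 0.0634). Actin regulators had 1 fall of 28, Arpc1, also adjusted over the list alone (adjusted p = 0.967). Nociceptor and mechanosensory channels had 1 rise of 25, ppk26, also adjusted over the list alone (adjusted p = 0.751). By limma 0 genes passed among neuronal identity genes (of 33, camera adjusted p = 0.127), channels (of 38, adjusted p = 0.236) and neuropeptides (of 54, adjusted p = 0.236), also adjusted over the list alone. The same was found for ligand-gated receptors (of 42, adjusted p = 0.26), microtubule regulators (of 36, adjusted p = 0.697), cell death genes (of 27, adjusted p = 0.751) and proteasome genes (of 40, adjusted p = 0.674), also adjusted over the list alone. Transcription factors of da neurons (of 33, adjusted p = 0.165) and fat body genes (of 28, adjusted p = 0.751) had 0 as well, or 1 and 3 falls adjusted over the list alone. For fat body genes the mean was 0.05, with a median of -0.03 and a direction of lower. The mean of actin regulators (-0.04) and the medians of nociceptor channels (-0.03) and microtubule regulators (-0.01) lay below 0 under a direction of higher.

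Of the 25 lists 12 passed camera between Kn ME and Ab ME and 2 passed fry, and 0 passed camera with estimated correlations. Another quantile normalization ended the calls of the dpr families (adjusted p = 0.317), the respiratory chain (0.207) and trachea (0.0506) and added heat shock (0.01) and immune response genes (0.0285). Centring ended that of the dpr families (0.073) and added heat shock genes (0.0477). The share of calls that were higher was 51.5% as deposited, 62% (62 of 100) after another quantile normalization and 45.3% (48 of 106) after centring. The count of 97 became 47 and 30 without Ab ME replicates 1 and 2 and 28, 30 and 26 without Kn ME replicates 1, 2 and 3, but 326 with array weights and 241 with only the 6 arrays compared. In simulated data with the unequal spread of these groups and 200 changed probe sets, 23 calls were false beside 151 recovered, or 13.2%. That share, too, depends on the number changed.

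Of the 992 probe sets called in Kn ME against Control, 902 were also called in Ab ME in the same direction, 558 higher and 344 lower, and 0 in opposite ones by limma, at unadjusted counts of 5665 and 3711 probe sets. The genes with the largest shared differences were Drsl5 (-5.19 in Ab ME and -4.50 in Kn ME), lncRNA:CR33948 (-5.08 and -4.39), CG7924 (-6.01 and -4.25), CG31323 (-5.49 and -3.88) and mthl6 (4.99 and 4.13), each with SE of 0.15 to 0.70.

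Because the Control arrays are shared, unchanged groups simulated against common controls gave a mean of 4.02 probe sets called in both in the same direction (0 to 19 over 100 draws), and lists of these sizes drawn independently would share 54.6 higher and 19.2 lower. Across all probe sets, which are not independent replicates, the log2 differences correlated at r = 0.862, against a simulated 0.744, and 81.6% had the same sign, against 73.8%. Their covariance was 0.52 against a simulated 0.105 (0.099 to 0.111), a difference of 0.415. Deviations that probe sets share were not simulated, so the simulated ranges may be too narrow. As 3 Control arrays cannot be divided into sets of at least 2, part or all of the excess may come from the shared controls. The F test over the 3 groups called 1809 probe sets, which became 1075, 1007 and 1125 without Ab ME replicates 1, 2 and 3. The shared count of 902 became 592, 568 and 582 without Ab ME replicates 1, 2 and 3, 375, 329 and 481 without Kn ME replicates 1, 2 and 3, 1481 without Control replicate 1, 553 with array weights and 313 with only the 6 arrays compared. A single opposite call appeared without Control replicate 1 and without Kn ME replicate 2.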

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

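The tests of a lower share of neurons, of the submitters' normalization, of the blood cell covariate, of strain variants and of Kn ME lying part of the way from Control to Ab ME were chosen only after the results were seen.

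Control probe sets of the array, which the comparisons did not use, differed from the Control arrays in both directions. A probe set for the 3' part of actin was higher by 1.01 log2 units in Ab ME and by 1.08 in Kn ME than in Control. A probe set for the 5' part of GAPDH was higher by 0.98 in Ab ME. Of the 183 control probe sets 2 were higher and 27 lower past the limma threshold in Ab ME, and 1 and 17 in Kn ME. The 2 largest falls, chosen after their values were seen, were -4.62 (SE 0.29) and -4.22 (SE 0.16) in Ab ME and -3.10 (SE 0.29) and -2.94 (SE 0.16) in Kn ME, from Control means of 8.71 and 10.8. Their targets are not given in the annotation used here, so whether either measures the sort marker mCD8:GFP, whose level bears on the share of marked cells, is unknown.

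In Ab ME and Kn ME 22 and 11 of 28 hemocyte genes were higher than in Control (adjusted p = 0.0973 and 0.129 with an estimated correlation) and 12 and 8 of 33 neuronal identity genes lower (adjusted p = 0.0555 and 0.0501 with an estimated correlation). A lower share of neurons alone would raise markers of every other cell type alike. The muscle median was -2.31 in Ab ME and the cuticle median -0.39 in Kn ME, beside hemocyte medians of 1.41 and 1.23. Cuticle scores were 2.87 to 3.18 in Control, 1.84 to 2.13 in Ab ME and 2.31 to 2.37 in Kn ME. Muscle scores in Kn ME (5.002 to 5.37) overlapped those of Control (5.198 to 6.01). The cuticle falls argue against a lower share of neurons as the only change, though lists were picked after their values were seen. After another quantile normalization the hemocyte medians were 1.179 and 1.067 and the neuronal identity medians -0.737 and -0.98. Each misexpression array lay beyond each Control array in both scores, which argues against a shift of whole arrays left by the submitters' normalization. A candidate explanation is more blood cells among the sorted cells: 15 further hemocyte genes, listed before that test, had medians of 2.20 in Ab ME and 1.24 in Kn ME, with 9 and 4 higher and 0 lower by limma. Hml and NimC1, abundant hemocyte genes chosen after their values were seen, averaged 8.66 and 8.73 in Control, 11.5 and 10.6 in Ab ME and 10.8 and 10.4 in Kn ME, and though the magnetic sort for mCD8:GFP would remove unmarked blood cells, 27 of the 28 listed hemocyte genes were above the median of all values in Control and 0 of the 28 were in another list. An effect of the misexpressed factors on these genes within neurons was not tested and stays open.

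Ab ME and Kn ME differed from Control in the same direction. The covariance of the log2 differences was 0.52 against at most 0.111 in sets simulated with shared Control arrays. This argues against noise of the Control arrays that is independent between probe sets as the whole cause. Deviations of the Control arrays that many probe sets share were not simulated, so the shared Control arrays stay open as a cause. A shift of whole arrays left by the submitters' normalization is argued against as the whole cause. After another quantile normalization and after centring, which remove such a shift, 740 and 1052 probe sets were still called in both in the same direction. Of the 902, 631 or 70% kept both calls after the former. The other splits drawn gave at most 10 and 23, but a processing difference that follows the groups would vanish in them too. That kind of difference stays open, and the hybridization controls BioB, BioC and BioDn were lower in both misexpression groups. A different share of blood cells cannot be told apart from the groups either, because the hemocyte score follows them: with it as a covariate 14 of the 902 kept both calls, the median size of the differences went from 1.95 to 1.39 in Ab ME and from 1.65 to 1.12 in Kn ME, and the median SE from 0.28 to 0.66 and to 0.55, so the calls ended through both. A shared effect of the misexpressed factors was not tested and stays open.

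A smaller set of probe sets differed between Kn ME and Ab ME. Kn ME lying part of the way from Control to Ab ME is argued against for all 97 at once, because 4 of them had a Kn ME mean beyond both other groups that differed from Control past a Bonferroni threshold over all probe sets, and 8 of the 97 had such a mean and were also called against Control, all higher in Kn ME. For the others it stays open, with 74 means inside the range and 15 outside it that did not pass against Control. The hybridization controls BioB, BioC and BioDn also lay between Control and Ab ME in Kn ME, so a technical difference that follows this order stays open too. Strain variants near inserted transgenes stay open: 1 pair of adjacent genes, Cyp4p1 and Cyp4p2, was among the 72 called genes, as many as in 3540 of 10000 random sets (permutation p = 0.35, 1-sided), and insertion sites are not given here. The different factors expressed are the biological difference that the design names, and that explanation was not tested.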

How the results depend on the processing

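The hemocyte score as a covariate was chosen only after the results were seen, and the other alternatives were planned. Directions of the named genes held under those planned beforehand except for kn between Kn ME and Ab ME, which did not pass in any case and moved from -0.01 to 0.012 without Ab ME replicate 2, 0.014 without Ab ME replicate 3, 0.028 without Kn ME replicate 2 (lowest -0.053, without Ab ME replicate 1) and 0.052 for the mean of its probe sets. Of 214 named gene results 206 passed as reported, and those no longer past the threshold numbered 19 with another quantile normalization, 3 with centring, 5 of 205 without dim probe sets (213 results measured), 13 with the trend and robust prior, 23 with array weights, 46 with only the 6 arrays compared, 10 with the mean of probe sets, and 7 to 51 with an array left out. With the hemocyte score 18 of the 214 passed and 13 changed sign, 8 of which had passed as reported, and 0 of the 13 passed with it. Examples in Ab ME are PPO2 (-3.41, SE 1.62), PPO1 (-1.95, SE 2.40), kn (1.89, SE 0.98) and ppk (1.704, SE 1.45). PPO1 and PPO2 belong to the hemocyte list, so the score contains their own values and their change of sign may in part be built in.

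Probe sets called numbered 2622 for Ab ME against Control, 992 for Kn ME against Control, 97 for Kn ME against Ab ME, 1809 among the 3 groups, and 902 shared in the same direction. These became 1002, 232, 23, 639 and 222 at an adjusted p under 0.01, where the stricter threshold is the cause, and 95, 47, 50, 79 and 45 with the hemocyte score as a covariate. Array weights gave 589 for Kn ME against Control, 326 for Kn ME against Ab ME and 553 shared. Only the 6 arrays compared gave 1726, 337 and 241 for the 3 comparisons and 313 shared. With an array left out the ranges were 1400 to 3249, 347 to 1609, 26 to 139, 1007 to 2317, 329 to 1481 shared, and 0 to 1 in opposite directions, by limma, where 5665 and 3711 probe sets had an unadjusted p under 0.05. Gene lists past camera numbered 18, 14 and 12, with ranges of 18 to 19, 12 to 16 and 9 to 13 with an array left out, and 0, 0 and 0 with an estimated correlation. Apart from the stricter threshold, the cause was not tested. Another quantile normalization (1814, 830 and 100) and centring (3127, 1147 and 106) left the counts within 1.5 times the reported ones.

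With the replicate number as a replicate block the counts were 2778, 1078 and 119 in the comparisons, 1900 among the 3 groups and 998 shared, with 18, 16 and 13 lists, and 20 of the 214 named gene results lost the call. Deviations of arrays with the same number correlated across probe sets at r = 0.034 to 0.272, with 0.211 to 0.272 for replicate 3. A batch shared by arrays of the same number therefore cannot be excluded, and the main fit does not include the number. Detection calls were not used here, so differences between dim probe sets may be limited by signal over background; leaving out the dim probe sets ended 5 of the 205 calls still tested and added 2.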

Other observations

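No test in this part was chosen only after the result was seen, and the splits of the arrays were planned.

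The 6 arrays of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. For probe sets, 1 of the 10 splits, the real one, gave as many in each comparison, with 2622, 992 and 97 against a highest other of 0, 0 and 0 by limma. For gene lists it was again 1 of the 10, with 18, 14 and 12 against a highest other of 11, 8 and 9. Among 100 splits drawn of the 280 into 3 groups, 1, the real one, gave as many as the 1809 probe sets of the F test, with a highest other of 747. This share is under 0.05 and argues against equal groups, though such a test takes the arrays as exchangeable, which the unequal spread of the groups puts in doubt. Among 100 drawn of 840, 1 gave as many as the 902 shared in the same direction, with a highest other of 20. These splits mix all 9 arrays, so they speak only against the 3 groups not differing at all. A difference of either group from Control would lower the count in mixed splits too. The agreement between Ab ME and Kn ME is therefore not tested by them. In opposite directions all 100 gave as many as the real 0, with a highest other of 0, but any split holds at least 0, so this comparison says nothing about chance.

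The hybridization control probe sets in this paragraph were lower in both misexpression groups, with Kn ME between Control and Ab ME, as on the first principal component. Other control probe sets did not follow this order: that for the 3' part of actin was higher by 1.01 in Ab ME and 1.08 in Kn ME. The cause was not tested. The hybridization controls BioB differed from Control by -1.44 to -1.50 in Ab ME and -0.79 to -0.84 in Kn ME, BioC by -1.31 and -1.25 in Ab ME and -0.66 and -0.61 in Kn ME, and BioDn by -0.47 and -0.91 in Ab ME and -0.19 and -0.41 in Kn ME. These probe sets were chosen after their values were seen.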
